A study of Mus musculus with 6 samples.

How the data were processed

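Bone marrow cells labelled as HSCs were sorted from wild-type mice into MHCII-hi and MHCII-lo fractions, and RNA was extracted with a micro-scale column kit and made into stranded poly(A) libraries, per the labels' protocols. The markers and boundaries of the gate are not given in the sources used here. The submitters' processing notes name fastp, HISAT2 and StringTie and the builds GRCm38 and mm10, with no versions or settings. HISAT2 aligns spliced reads and StringTie estimates transcript levels, and how reads shared by several genes were treated is not given in the sources used here.

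Each deposited file holds a gene symbol and 1 value per gene for 1 library, in 30803 rows with 2 decimals. The file headers name the library and not the unit. The deposited values were taken as FPKM as StringTie writes it, because they have decimals, sum to about the same but not an equal total in each library, and so are neither counts nor TPM of a full table. FPKM is normalized to library size and transcript length by the authors, so a rise of abundant transcripts lowers the values of all others. The depth is unknown, and no counting interval was computed. Symbols that occur more than once numbered 67. The row with the highest mean kept the symbol and the other 70 rows were kept under a row name. Gene identifiers, coordinates, transcript length and GC content came from the GENCODE M21 annotation of GRCm38, which matched 96.4% of the symbols to a single gene.

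The 6 libraries were grouped by the cell subtype in the labels. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12295 in all. Values were transformed to log2(FPKM + 1), and MHCII-hi was compared with MHCII-lo in limma 3.58.1 under R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes on the log2(FPKM + 1) scale understate the change of low genes, and folds given as "n-fold" for a gene are ratios of mean FPKM, while "at least 2-fold" means a change of 1 or more on the log2(FPKM + 1) scale. Values are means ± SD over 3 libraries unless SE is named.

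The test, the filter, 32 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Ciita. It also took, per direction, the 10 largest changes past the threshold whose groups did not overlap, leaving out predicted gene models. From each list it took up to 4 members with the largest changes past the threshold, or where none passed the 2 with the smallest p. The gate genes Kit, Ly6a, Slamf1, Cd48, Cd34, Flt3 and Procr were always taken. Other genes are named where they complete a count of 5 or fewer, or were chosen after their values were seen: Cd79a, Pax5, Vpreb1, Ighm, the accessory class II genes, S100a9, Mpo, Elane, Prtn3, F13a1, Prg2, Pf4, Xist and the genes that open the closing section.

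Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, when at least 5 members passed the filter. This left 31 lists. The list of sex-linked genes had 4 tested members and is given as values. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction without reference to other genes, were run beside it. Fry called 21 lists higher and 10 lower. Each list's median was also set against 10000 random lists matched on expression and transcript length.

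The fit was tested on simulated data made from the 12295 genes' own means and spreads, with 50 genes changed at each size. It called 44% of genes changed by 0.25 on the log2 scale, 82% at 0.5, 94% at 1 and 100% at 2, and 0.0992% of unchanged genes. The simulation left 12095 genes unchanged, while 8330 were called in the data. The adjusted threshold depends on that share, so these rates do not describe the real comparison. The alternatives were pseudocounts of 0.1 and 0.01, no filter and a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, no mean-variance trend, array weights, the replicate number as a block and each library left out. Added after the data were seen were limma's treat test against 2-fold, the removal of immunoglobulin segments, and the removal of each library's trend on transcript length and GC content. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. Count-based tests were not run because the values are not counts.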

Results

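Bone marrow cells labelled as hematopoietic stem cells (HSCs), the cells that renew the blood, were sorted from wild-type mice at 5 months into fractions with high and low surface MHC class II. MHC class II molecules present peptides to helper T cells and are best known from B cells, dendritic cells and macrophages. Poly(A) RNA-seq gave 6 libraries in 2 groups, MHCII-lo and MHCII-hi, with 3 libraries each (n = 3 per group throughout). The deposited values are one number per gene and library, read here as FPKM (fragments per kilobase of transcript, scaled to library size), a unit inferred from the values. Read depth is unknown. The FPKM of a library summed to 306496 ± 515 (SD, n = 3) in MHCII-lo and 333432 ± 92.5 (SD, n = 3) in MHCII-hi. Genes at 1 FPKM or more numbered 12100 ± 18.0 in MHCII-lo and 12402 ± 18.9 in MHCII-hi. The most abundant transcript was mt-Co1 in all 6 libraries.

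The libraries of a group were nearly identical. Across the 12295 tested genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) lay between 0.990 and 0.994 within a group and between 0.905 and 0.909 across groups. The first principal component held 89.5% of the variance and separated the groups. The median coefficient of variation (CV) between the 3 libraries at 10 to 100 FPKM was 2.63% in MHCII-lo and 3.28% in MHCII-hi. At 100 to 1000 FPKM it was 1.48% and 1.68%. The labels do not say that the libraries came from separate animals, so the p-values given here measure only the spread between these libraries, which may be technical. With so small a spread, changes of a few percent passed the test, and the size of a change is therefore given first.

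The comparison asked how the transcriptome of the MHCII-hi fraction differs from that of the MHCII-lo fraction in unperturbed mice. The sort was checked first on the MHC class II genes themselves. The alpha and beta chains of the classical class II molecules were 10.97 to 15.1 times higher in MHCII-hi. H2-Aa (ENSMUSG00000036594.15; GRCm38 chromosome 17, 34282744 to 34287823, minus strand) went from 7.34 ± 0.0361 to 80.5 ± 0.811 FPKM, a log2 change of 3.29 ± 0.02 (SE). H2-Ab1 (chromosome 17, 34257689 to 34269419, plus strand) rose from 9.88 ± 0.338 to 116 ± 2.01 FPKM. H2-Eb1 (chromosome 17, 34305867 to 34316674, plus strand) rose from 5.65 ± 0.223 to 85.5 ± 2.47 FPKM. Cd74, the invariant chain that escorts class II molecules (chromosome 18, 60803848 to 60812652, plus strand), rose 11.5-fold, from 49.98 ± 1.01 to 574 ± 5.03 FPKM. Ciita, the master transactivator of class II genes (chromosome 16, 10480059 to 10528418, plus strand), rose 8.59-fold from a low level, 0.387 ± 0.123 to 3.32 ± 0.186 FPKM. All 5 are annotated as protein-coding. The limma adjusted p-values were 2.64e-09 for H2-Aa, 6.42e-09 for H2-Ab1, 9.97e-09 for H2-Eb1, 9.58e-10 for Cd74 and 6.70e-06 for Ciita, and each gene was higher in every MHCII-hi library than in every MHCII-lo library.

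Of the 10 tested genes on the MHC class II list, 9 rose and 1 did not pass the test, with the same counts when adjusted over the list alone. The accessory genes of peptide loading rose less: H2-DMb1 rose 1.47-fold, H2-DMb2 2.80-fold, H2-Oa 2.70-fold and H2-Ob 3.20-fold. H2-DMa stood at 19.8 ± 1.04 against 21.1 ± 0.425 FPKM and did not pass (limma adjusted p = 0.0972). The list's median log2 change was 1.52 (camera in limma, adjusted p = 8.91e-08, and 0.0222 with an estimated correlation).

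B cell genes rose together with the class II genes. All 21 tested members of the B cell list were higher in MHCII-hi, 19 of them at least 2-fold, and the list's median log2 change was 2.64. Igkc, the constant region of the kappa light chain, went from 210 ± 29.96 to 6698 ± 82.6 FPKM. Jchain, which joins secreted IgA and IgM into polymers, rose 19.4-fold, from 17.6 ± 1.91 to 341 ± 3.52 FPKM. Fcmr, the IgM receptor, went from 0.103 ± 0.0907 to 11.5 ± 0.341 FPKM. The signalling chain Cd79a rose 11.7-fold and the B cell transcription factor Pax5 12.3-fold. The pre-B cell receptor gene Vpreb1 rose less, 1.68-fold. The list had a camera adjusted p of 2.57e-15 in limma, and 0.0133 with an estimated correlation, and all 21 also passed when adjusted over the list alone.

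Immunoglobulin gene segments were the largest increases in the dataset. Of 216 tested segments, 208 rose and none fell, and all 208 rose at least 2-fold. Their share of the library's FPKM was 0.415 ± 0.0367% in MHCII-lo and 8.30 ± 0.0385% in MHCII-hi. The 10 largest increases of named genes were all of this kind. They included Ighv8-8, from 16.6 ± 3.13 to 763 ± 21.6 FPKM, Igkv3-2, from 9.41 ± 2.43 to 547 ± 12.1 FPKM, and Igha, the IgA heavy chain, which rose 39.3-fold to 1033 ± 6.78 FPKM. Igkj4 headed the ranking, but its MHCII-lo level rests on 1 library, with 0.39, 0.61 and 22.76 FPKM against 331 to 354 FPKM in MHCII-hi. Similar segments can share reads, so the level of any single one is uncertain.

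**Figure D1:**
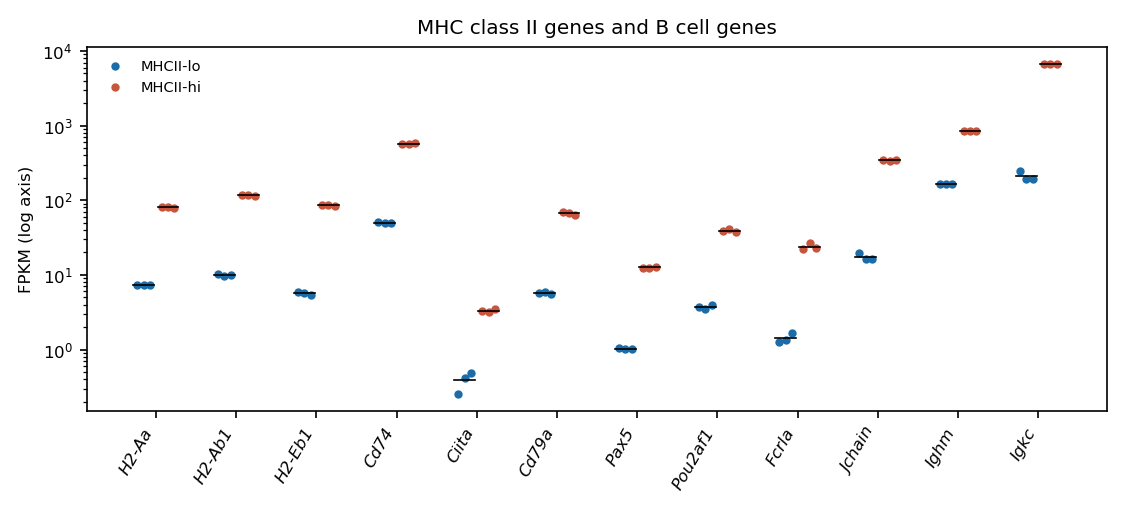
FPKM per library on a log axis for 5 MHC class II genes and 7 B cell genes, with points for the 3 MHCII-lo (blue) and 3 MHCII-hi (red) libraries and a black line at each group's mean. Every MHCII-hi point lies above every MHCII-lo point of the same gene, with Cd74 at 574 against 49.98 FPKM and Igkc at 6698 against 210 FPKM.

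Other lymphoid genes moved the same way with smaller folds. On the lymphoid priming list, 23 of 24 tested genes rose and none fell, with a median log2 change of 0.67 (camera in limma, adjusted p = 6.54e-11, and 0.0133 with an estimated correlation). The recombinase gene Rag1 rose 6.49-fold, the B lineage factor Ebf1 7.93-fold and the chemokine receptor Ccr7 6.37-fold. Among 27 T and NK cell genes, 20 rose, 4 did not pass and 3 fell, namely Cd3d, Nkg7 and Gzma (camera in limma, adjusted p = 7.49e-06, and 0.0296 with an estimated correlation). The T cell coreceptor Cd4 rose 4.61-fold to 4.14 ± 0.191 FPKM, and the T cell receptor constant region Trac 2.31-fold to 27.1 ± 2.20 FPKM.

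Among 25 dendritic cell and macrophage genes, 15 rose, 5 fell and 5 did not pass. The complement genes C1qa and C1qb rose 6.91-fold and 6.86-fold, both to under 6 FPKM, and Cd209a rose 2.89-fold to 31.4 ± 1.53 FPKM. Ctss, Naaa, Cst3, Adgre1 and Bst2 fell. The list's adjusted p was 0.000823 (camera in limma, 0.0343 with an estimated correlation), and its call was lost among genes with a mean of at least 5 FPKM (adjusted p = 0.0658, median log2 change 0.07).

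The genes that define stem cell gates did not pass as a list at the expression minimum used, and passed as higher without it. Kit, the stem cell factor receptor, was level at 10.9 ± 0.0306 FPKM in MHCII-lo and 10.8 ± 0.208 FPKM in MHCII-hi (limma adjusted p = 0.880). Cd34 stood at 14.8 ± 0.281 and 15.7 ± 0.414 FPKM (limma adjusted p = 0.0631, passing under 3 alternative settings). Ly6a, which encodes Sca-1, rose 3.05-fold from 4.78 ± 0.214 to 14.6 ± 0.517 FPKM, and Flt3 rose 1.51-fold to 14.8 ± 0.384 FPKM. Cd48, which long-term HSCs lack at the surface, fell from 121 ± 1.32 to 93.1 ± 1.89 FPKM, by 0.37 on the log2 scale, and by 0.21 once the trend on transcript length and GC content was removed. Slamf1 (CD150), at 0.210 ± 0.0656 and 0.387 ± 0.0961 FPKM, and Procr, at 0.233 ± 0.0551 and 0.763 ± 0.0961 FPKM, lay below the expression minimum and were not tested. Of the 6 gate genes tested, 3 rose, 1 fell and 2 did not pass (camera in limma, adjusted p = 0.0799, and 0.209 with an estimated correlation). Without a filter, which brings in Slamf1 and Procr, the list's 8 genes passed as higher in camera at an adjusted p of 0.00903. That setting also widens the comparison to 27715 genes, so the pass cannot be laid to Slamf1 and Procr alone. The other alternatives of the fit gave 0.0509 to 0.104, and fry called the list higher (adjusted p = 1.52e-05).

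Only 19 of the 34 long-term stem cell markers reached the minimum, and of these 11 rose, 3 fell and 5 did not pass. The transcription factor Gata2 rose 2.43-fold to 23.8 ± 0.780 FPKM. Lmo2, Tal1 and Bmi1 fell. The list passed with the preset correlation (camera in limma, adjusted p = 0.00548), but the adjusted p was 0.0992 with an estimated correlation and 0.184 among genes with a mean of at least 5 FPKM. The list of genes raised in aged HSCs did not pass (camera in limma, adjusted p = 0.481). On it 5 genes rose, 5 fell and 8 did not pass, with Cd38 8.07-fold higher and Aldh1a1 lower, at 2.92 against 5.88 FPKM.

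Cell cycle genes were lower in MHCII-hi, with modest folds. No gene of the S phase list rose, 38 of 43 fell, and the median log2 change was -0.48. Dut, which clears dUTP, fell from 48.5 ± 1.46 to 21.1 ± 0.921 FPKM, and Rfc4, a clamp loader subunit, fell from 33.6 ± 0.708 to 15.2 ± 1.26 FPKM. Of 38 mitosis genes, 33 fell, among them Pbk, Cdk1 and Ccnb1, with a median log2 change of -0.32. Mki67, Ube2c and Cdca3 rose. Conversely, 15 of 19 tested quiescence genes and cell cycle inhibitors rose, with Foxo1 2.87-fold, Hes1 2.98-fold and Egr1 2.74-fold higher, while Cdkn2c, Cdkn2d and Gfi1 fell. In camera of limma the adjusted p was 7.73e-09 for S phase, 9.29e-06 for mitosis and 1.87e-05 for quiescence, and 0.0296 for each of the 3 with an estimated correlation. Egr1 and 4 other quiescence genes that rose are also on the immediate early list, and of the 14 tested quiescence genes outside it 10 rose and 3 fell, with a median log2 change of 0.26. Cell type lists moved in the same comparison, B cell genes by a median of 2.64 and erythroid genes by -0.51, so a change of cycling within a cell type was not measured.

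Ribosomal protein and respiratory chain genes fell most uniformly. Of the 78 cytosolic ribosomal protein genes, 72 fell, 3 did not pass and 3 rose, namely Rps10, Rps26 and Rpl35, with a median log2 change of -0.74. Rps19 fell from 101 ± 0.269 to 34.8 ± 0.870 FPKM and Rps21 from 259 ± 4.49 to 89.6 ± 7.05 FPKM. All 59 tested nuclear genes of oxidative phosphorylation fell, with a median log2 change of -0.67. Atp5e, a subunit of ATP synthase, fell from 39.3 ± 1.17 to 13.9 ± 0.829 FPKM and Cox7a2, of cytochrome c oxidase, from 66.3 ± 2.29 to 24.4 ± 2.24 FPKM. The 13 mitochondrially encoded genes rose, with a median log2 change of 0.62, and mitochondrial transcripts made up 8.87 ± 0.0742% of the FPKM in MHCII-lo and 12.5 ± 0.0218% in MHCII-hi. The camera adjusted p in limma was 3.47e-19 for ribosomal proteins, 9.58e-15 for oxidative phosphorylation and 2.76e-10 for mitochondrially encoded genes. With an estimated correlation the first 2 had an adjusted p of 0.0138 and 0.0133, and the mitochondrial call was lost at an adjusted p of 0.0539. Quantile normalization reduced the mitochondrial median to 0.22.

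Transcript length moved with the groups. Outside the immunoglobulin segments, the 10% of tested genes with the shortest transcripts (up to 578 bases) had a median log2 change of -0.20, and the 10% with the longest 0.03. Random lists matched to the ribosomal list on level and length had a median of -0.255, with 95% of them between -0.378 and -0.116, against -0.74 for the list. For oxidative phosphorylation the random median was -0.224, against -0.67.

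**Figure D2:**
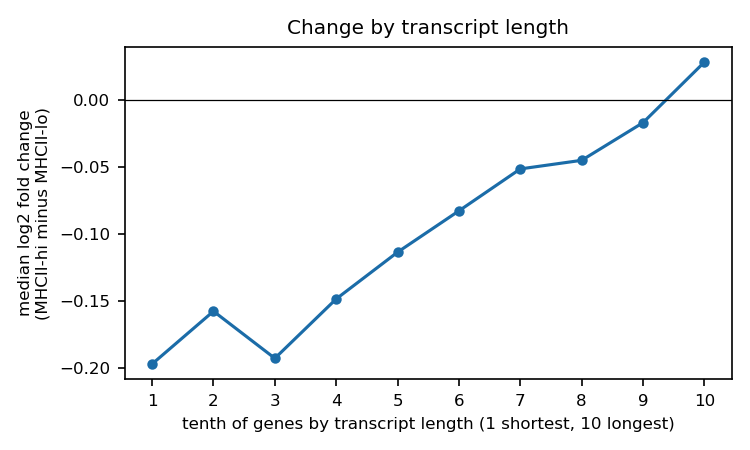
Median log2 fold change (MHCII-hi minus MHCII-lo, on log2(FPKM + 1)) in 10 equal bins of the tested genes by transcript length, without immunoglobulin segments. The median goes from -0.20 in the shortest bin to 0.03 in the longest.

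Immediate early genes, which respond within minutes to stimulation or tissue handling, rose in 25 of 27 cases. Egr1 went from 67.4 ± 0.658 to 184 ± 1.34 FPKM, Zfp36 from 257 ± 2.44 to 556 ± 7.72 FPKM and Dusp5 rose 2.39-fold, while Atf3 fell and Dusp2 did not pass. Of 30 NF-kB and inflammatory genes, 20 rose and 5 fell, with Ccl3 at 500 ± 7.07 against 250.4 ± 4.18 FPKM and Cxcl2 1.91-fold higher. Of 45 interferon response genes, 24 rose, 8 fell and 13 did not pass, with Ly6a and Oas2 at least 2-fold higher. The camera adjusted p in limma was 3.66e-12, 0.000200 and 0.000766 for these 3 lists, and 0.0133, 0.0296 and 0.0296 with an estimated correlation.

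Both groups held abundant granulocyte transcripts. The 30 neutrophil and monocyte genes made up 7.70% of the FPKM in MHCII-lo and 8.51% in MHCII-hi, and S100a9 reached 5900 ± 12.4 and 7631 ± 48.7 FPKM. The list moved both ways, with 13 genes higher, 15 lower and 2 not past the test. Its median log2 change was -0.11 and its mean 0.05, and it did not pass (camera in limma, adjusted p = 0.720). The granule genes of maturing neutrophils Ngp, Mmp8, Mmp9 and Lcn2 rose 2.70-fold, 2.65-fold, 2.61-fold and 2.15-fold, and with quantile normalization the log2 change of Ngp was 0.79 against 1.43. Prtn3, of early granules, fell from 495 ± 2.36 to 267 ± 6.93 FPKM and F13a1, of monocytes, from 182 ± 1.83 to 86.4 ± 1.30 FPKM. The early granule genes Mpo, at 1389 and 1105 FPKM, and Elane, at 1121 and 782 FPKM, also fell.

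**Figure D3:**
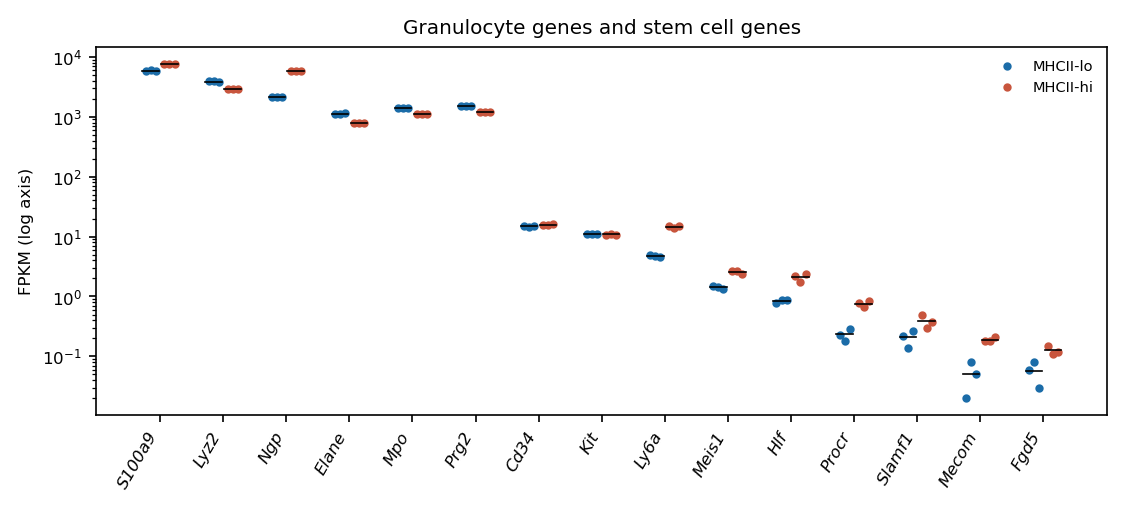
FPKM per library on a log axis for 6 granulocyte genes and 9 stem cell genes, with points for the 3 MHCII-lo (blue) and 3 MHCII-hi (red) libraries and a black line at each group's mean. S100a9 stands at 5900 and 7631 FPKM, Kit at 10.9 and 10.8 FPKM, and Procr and Slamf1 lie below 1 FPKM in all 6 libraries.

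Erythroid genes fell in 21 of 25 cases, with Hbb-bt going from 147 ± 1.59 to 69.4 ± 4.66 FPKM and Rhd from 19.2 ± 0.886 to 9.08 ± 0.176 FPKM, and only Nfe2 and Zfpm1 rose. Of 18 tested megakaryocyte and platelet genes, 13 rose and none fell, with Thbs1 and Nbeal2 among the largest, while Pf4 stood at 8.31 ± 1.22 and 9.56 ± 1.15 FPKM and did not pass. Of 14 mast cell, basophil and eosinophil genes, 9 rose, with the mast cell protease Cpa3 2.08-fold and the basophil protease Mcpt8 1.74-fold higher, and Prg2 fell. The camera adjusted p in limma was 6.87e-05, 8.19e-06 and 0.000144, and 0.0296, 0.0343 and 0.0296 with an estimated correlation.

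The remaining lists moved less or in both directions. Of 17 TGF-beta and BMP genes, 12 rose and 2 fell, with Thbs1 and Tgfbr2 higher (camera in limma, adjusted p = 0.000486, and adjusted p = 0.0879 with an estimated correlation). Of 10 Wnt and Notch genes, 7 rose and 2 fell, the latter Ctnnb1 and Lrp5 (camera in limma, adjusted p = 0.0261, and adjusted p = 0.144 with an estimated correlation). Of 17 niche adhesion genes, 9 rose and 6 fell, with the egress receptor S1pr1 3.90-fold higher (camera in limma, adjusted p = 0.0472, and adjusted p = 0.131 with an estimated correlation). No call was made in limma's camera for antigen processing and costimulation (adjusted p = 0.0647, 10 rose and 4 fell of 18), MHC class I presentation (adjusted p = 0.430, 6 rose and 12 fell of 20) or glycolysis (adjusted p = 0.187, 6 rose and 12 fell of 23). The same held for heat shock and unfolded protein genes (adjusted p = 0.0885, 7 rose and 15 fell of 24) and p53 and DNA damage genes (adjusted p = 0.188, 9 rose and 7 fell of 25). It also held for lysosome and autophagy genes (adjusted p = 0.976, 13 rose and 15 fell of 32) and endothelial and stromal genes (adjusted p = 0.742, 2 rose and 2 fell of 8). The last 2 lists had medians of -0.01, against an upward camera statistic. The Y-linked gene Ddx3y was present in all 6 libraries, at 15.3 ± 0.0872 and 13.4 ± 0.117 FPKM, and Xist stayed under 0.1 FPKM.

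**Figure D4:**
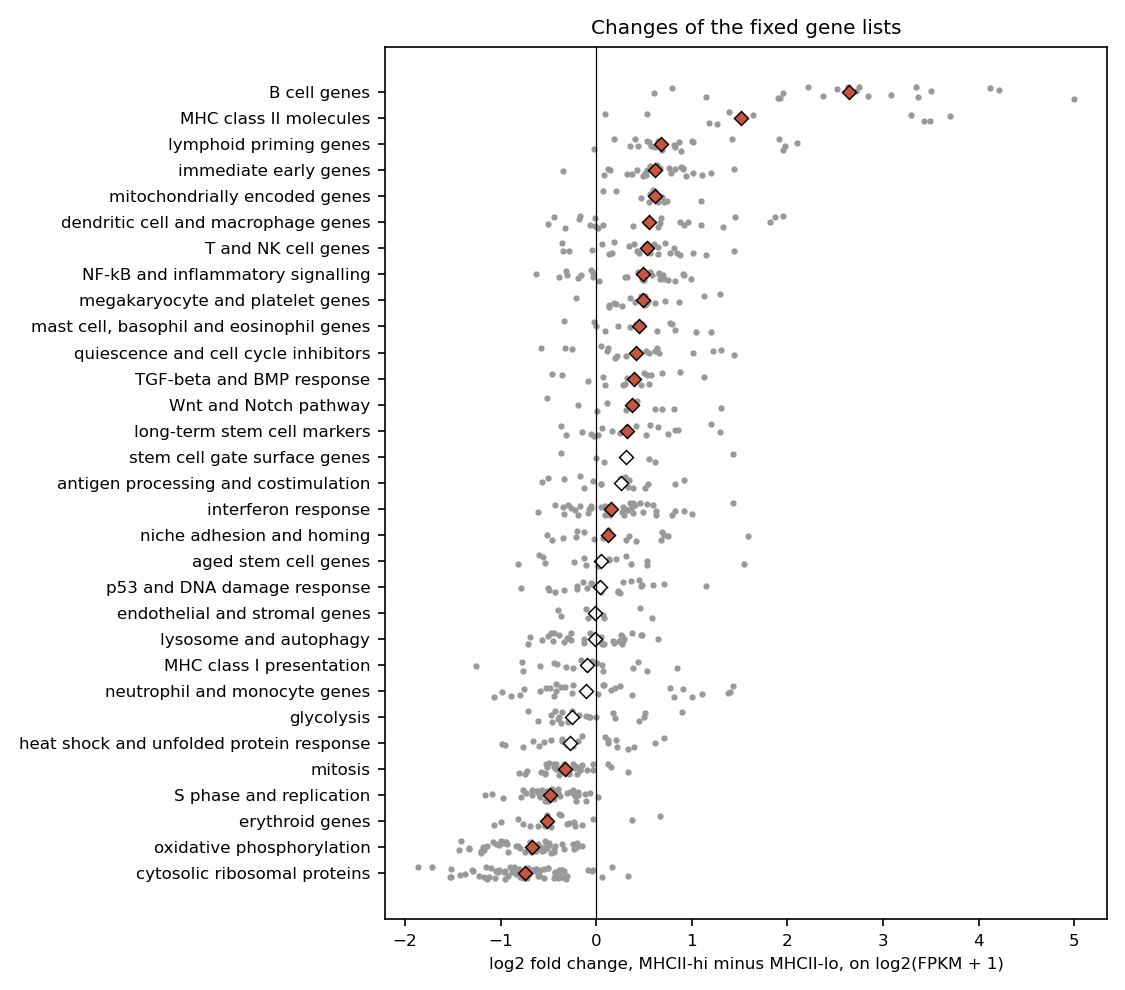
Log2 fold change (MHCII-hi minus MHCII-lo, on log2(FPKM + 1)) of each tested member (grey points) of the 31 tested gene lists, with a diamond at each list's median, filled where the camera adjusted p was under 0.05. B cell genes have the highest median, 2.64, and cytosolic ribosomal proteins the lowest, -0.74.

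Over all 12295 tested genes, limma called 3348 higher and 4982 lower in MHCII-hi at an adjusted p under 0.05, and 3965 did not pass. Of these, 454 rose and 180 fell at least 2-fold, and without immunoglobulin segments the count of such increases was 246. These counts depend on the pseudocount: 632 rose and 315 fell at least 2-fold with 0.1, and 682 and 346 with 0.01. In 72.8% of the genes the 3 libraries of a group all lay above the 3 of the other, against 10% if all libraries were interchangeable. Libraries of a group were nearly identical, so this share does not bear on chance. Among the largest decreases were Nnt, a mitochondrial transhydrogenase, from 15.4 ± 0.366 to 3.25 ± 1.27 FPKM, the RNA-binding Lsm5, from 29.99 ± 2.09 to 7.40 ± 2.09 FPKM, and Rpl22l1, from 75.0 ± 1.66 to 22.1 ± 1.13 FPKM. Rpl17 also fell, from 191 ± 32.4 to 51.2 ± 3.14 FPKM. The median change over all tested genes was -0.08 on the log2 scale. Camera called 16 lists higher and 5 lower of 31 tested, and 11 higher and 5 lower with an estimated correlation. At the preset correlation each of the 9 other splits of the libraries gave 17 to 21 lists. The number of calls therefore does not set this grouping apart. All those splits mix both fractions unequally on each side, so they keep part of the contrast and are no measure of chance. With an estimated correlation they gave 0 lists, but there the difference between the fractions enters the spread, which works against calls. The counts adjusted over the list alone differed from those over all genes for 8 of the 31 lists. They were 9 lower for interferon, 14 higher for megakaryocyte, 22 lower for erythroid, 14 lower for glycolysis, 73 lower for ribosomal, 26 higher for immediate early, 8 higher for heat shock and 6 lower for NF-kB genes.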

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

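The tests against 2-fold, without immunoglobulin segments, and after removal of the length and GC trend were chosen after the results were seen. Counts of 2-fold changes depended on the pseudocount, which compresses low genes by construction: 315 genes were lower at least 2-fold with 0.1 and 346 with 0.01, against 180, and 682 were higher with 0.01, against 454. With a mean of at least 5 FPKM, where fewer genes are tested, 2210 genes rose, against 3348. The mean r between groups, 0.907, moved to 0.889 with a pseudocount of 0.1 and to 0.838 with that filter. Tested against a change of 2-fold instead of any change, limma called 355 genes, 313 higher and 42 lower. Without immunoglobulin segments, 246 genes were higher at least 2-fold.

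Leaving out each library in turn gave 7593 to 7952 genes changed, 3071 to 3168 higher and 4501 to 4807 lower, fewer than the 8330, 3348 and 4982 with all 6 because fewer libraries enter. It gave 441 to 464 genes higher and 175 to 192 lower at least 2-fold, 20 to 21 lists and 140 to 141 of the named genes. No result changed direction where it was called. With the replicate number as a block, 3222 genes were higher and 4809 lower. Same-numbered libraries deviated together with a correlation of 0.00190 to 0.0804 across genes, and 4 of the 6 libraries deviated most like their own number. These correlations are weak and the spread within a group is small, so whether the numbers pair the libraries stays open. Median-of-ratios scaling gave 3584 higher and 4620 lower, and no scaling moved the median change by over 0.1. In 9 list tests a call was lost and in 5 gained, over the alternatives of the fit. Lost were niche adhesion in 5 settings (adjusted p in limma from 0.0501 to 0.0598), Wnt and Notch after the length and GC trend was removed (0.156) and at 5 FPKM (0.155), and the 2 lists named in the report at that filter. Heat shock (0.0110), glycolysis (0.0275) and gate genes (0.00903) passed without a filter, heat shock also after the length and GC trend was removed (0.0310), and antigen processing without immunoglobulin segments (0.0429). Kit passed as lower after the length and GC trend was removed, by -0.08 (limma adjusted p = 0.0465). Depth is unknown, so the precision of low genes rests on the spread between libraries alone.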

Other observations

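The tests of explanations below were chosen after the results were seen, except those on other splits of the libraries at the preset correlation; the named genes of the first paragraph were likewise picked from the data. Antibody constant regions rose by different folds. Igha rose 39.3-fold to 1033 ± 6.78 FPKM, Ighg2c 34.9-fold to 604 ± 2.39 FPKM and Ighg2b 16.1-fold to 337 ± 4.92 FPKM. Ighg3 rose 45.4-fold to 26.8 ± 1.66 FPKM and Ighg1 14.9-fold to 27.6 ± 0.514 FPKM. Of those that are not class-switched, Ighd rose 10.5-fold from 1.24 ± 0.0551 FPKM and Ighm 5.20-fold, from 164 ± 1.26 to 855 ± 1.74 FPKM. The difference between these folds was not tested. Among the genes picked, some that plasma cells express also rose, but no list of plasma cell genes was tested. Irf4 rose 9.01-fold from 2.22 ± 0.174 FPKM, Tnfrsf17 (BCMA) 12.9-fold to 3.36 ± 0.252 FPKM, Derl3 9.46-fold to 6.62 ± 0.531 FPKM, Prdm1 3.47-fold and Sdc1 (CD138) 2.94-fold. Xbp1, which other secretory cells also use, went from 54.0 ± 0.395 to 68.3 ± 1.53 FPKM.

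Lars2, a mitochondrial leucyl-tRNA synthetase, fell from 20.6 ± 0.305 to 5.74 ± 0.289 FPKM. The unnamed model CT010467 fell from 611 ± 12.1 to 277 ± 5.17 FPKM, and AC124742 from 47.0 ± 3.93 to 10.9 ± 1.30 FPKM. Whether the reads counted here come from these genes themselves was not tested.

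MHC class II and B lineage transcripts rose together. Reads shared between immunoglobulin segments do not account for this, since all 17 tested B cell genes outside those loci rose as well. A candidate explanation is a larger share of B lineage cells or their RNA in the MHCII-hi libraries: those 17 genes had a median log2 change of 2.63 and a median fold of 8.65, near the median of 11.6 for H2-Aa, H2-Ab1, H2-Eb1 and Cd74. Among the 21 tested genes held by the dendritic cell and macrophage list alone, 14 rose and 3 fell. Their largest change on the log2(FPKM + 1) scale was 1.87 (C1qb), below that B cell median. That scale compresses low genes, and C1qb rose 6.86-fold, from 0.820 to 5.62 FPKM. Folds also depend on each gene's MHCII-lo level, so this comparison cannot exclude dendritic cells and macrophages as the source of the B lineage rise. For the class II rise these cells stay open as a source as well. The largest ratio of mean FPKM among those 21 genes was 6.91-fold (C1qa), against 10.97-fold for the lowest of these class II genes. The B cell genes' median of 8.65 also lies below 10.97, so this comparison cannot tell the sources apart. Whether HSCs themselves carry class II transcripts at the higher level was not tested and stays open, and the gate markers that would exclude B cells are not given in the sources used here.

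Ribosomal protein and oxidative phosphorylation genes fell together. Transcript length is not the whole cause, since after removal of the length and GC trend the ribosomal median was still -0.68 and that of oxidative phosphorylation -0.63. Reads lost to ribosomal pseudogenes would raise these, but 90 of 139 fell and 7 rose, with a median of -0.50. Scaling by abundant immunoglobulin and mitochondrial transcripts is argued against by median-of-ratios scaling, which left the ribosomal median at -0.71. A biological difference between the groups, in the mix of cells or within a cell type, stays open and was not tested. Another technical difference between the groups cannot be told apart from it, since the 3 libraries of a group may come from one pool. Cell type lists moved in the same comparison, B cell genes by a median of 2.64 and erythroid genes by -0.51.

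Granulocyte transcripts were abundant in both groups, and the stem cell markers Procr and Slamf1 lay below 1 FPKM. Of the 30 neutrophil and monocyte genes, 18 stood at 100 FPKM or more in both groups, as would be seen if many cells in the libraries were not stem cells, while 19 of the 34 long-term stem cell markers reached a mean of 1 FPKM. No library of purified stem cells was used here, and stem cell regulators can be low in any cell, so the share of such cells stays open. The 3 libraries of a group may come from one pool of cells: antibody variable segments, whose use differs between animals, varied by a median CV of 5.37% over 125 segments in MHCII-hi, against 4.01% for other genes matched on signal. In a fit of the CV on signal, the part that did not fall with signal was 0.843% in MHCII-lo and 1.02% in MHCII-hi. Pools that each mix many animals could also give a small spread, and the labels do not decide it.

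With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 8330 genes and the highest other 1 gene, and at least 2-fold it gave 634 against 1. In each other split both fractions lie on each side, so the difference between them enters the spread. Few calls there follow from the design, and these counts do not bear on chance. For the gene lists at the preset correlation the real split gave 21 and the 9 others 17 to 21, so that 2 of the 10 splits had as many. An estimated correlation was chosen as a test of the splits after these counts were seen. With it the real split gave 16 lists and the highest other 0. The difference between the fractions also enters that estimate in the other splits, so the 0 does not bear on chance either. Those splits mix the fractions unequally and keep part of the contrast, so their counts at the preset correlation are no measure of chance.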
